A study of Yarrowia lipolytica with 6 samples.

How the data were processed

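Total RNA of 6 cultures of the oleaginous yeast Yarrowia lipolytica was measured on single-colour NimbleGen expression arrays with the dye Cy3. The labels place 3 cultures in a control group, the Ura+ derivative of strain Y4184, and 3 in a group in which the SNF1 gene of the same strain background was deleted entirely. The labels describe each sample as a biological replicate from a separate culture, so the spread within a group is between cultures. Cultures were harvested in mid-log phase, at an optical density of 2.0 at the usual wavelength, in synthetic medium with 2% glucose and 0.67% yeast nitrogen base at 30 °C, per the labels' protocols. The labels give the aeration with a misspelt word that reads as anaerobic, and whether the cultures had air is not settled here. The snf1 deletion samples carry the numbers 43, 46 and 47 in their titles, and the labels do not say what these numbers stand for. They are called replicates 1, 2 and 3 here.

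The deposited scanner files hold 1 intensity per spot, extracted from the Cy3 image with NimbleScan 2.4.31, per the file headers, with neither background subtraction nor normalization. The array carries 6708 features, which the series describes as genes of Y. lipolytica. Of these, 6707 have 14 probes each and 1 has 1 probe. In the files each of the 93899 distinct 24-mer probes is present 4 times per array, whereas the series text speaks of 3 copies and of mismatch partners. The mismatch column was 0 on all spots of all 6 arrays, so no mismatch signal was used. Each array also carries 13711 spots of random sequence. The authors also deposited a table of 1 intensity per feature and array, made with RMA per the submitters' processing notes, which give neither a version nor settings. Set against the scanner files, the deposited values are on a linear scale and run the same way. Their log2 correlated with the summaries described next at 0.991 to 0.992 per array, and their column medians lay between 4627 and 4856.

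The features are identified in the files by running numbers only, and the files do not pair them with gene names. None of the 6708 identifiers matched the table of RefSeq genes at hand (assembly ASM176148v1), and the probe sequences were not used here. For that reason no feature is given a gene name, a genomic position or a function. The 24 gene lists fixed before the data were examined (lipid metabolism, glucose repression and others) could not be tested, and neither could the test of the SNF1 feature by name.

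Gene summaries followed the steps of RMA. Spot intensities were corrected with normexp (saddle-point estimates, offset 50), quantile normalized between arrays and put on the log2 scale, the 4 copies of a probe were averaged, and the probes of a feature were combined by median polish. The offset and the residual background compress the changes of dim features. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on all 6 arrays, no covariate, no filter), testing both directions, with Benjamini-Hochberg adjustment over the 6708 features and a threshold of 0.05. A second count required a fold of at least 2. A feature was called above background on an array if the median signal of its probes exceeded the 95th percentile of that array's random spots. A feature below it on every array of a group has only a bound, and its fold is given as at least the value against the lowest normalized signal of the features above background on those arrays. The number of arrays, 3 per group, limits the precision of all comparisons.

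The rule for named features, fixed before the data were examined, allowed at most 2 identifiers per direction among those past the threshold. It names 1 feature. Other features named were chosen after their values were seen. The alternatives fixed in advance covered 2 other background settings, median scaling, cyclic loess, the mean of probes, every spot in the median polish, a filter on dim features, the deposited table, eBayes with an intensity trend and robust estimation, a replicate block, limma's treat against a fold of 1.5, and each array left out in turn. Array weights were added after the data were seen. Every array came from an image of its own. The image numbers and the order of image analysis in the file headers sort the arrays by group, so an effect of processing order cannot be told apart from the group.

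The procedure was tested on simulated data: 6708 features with the observed means and within-group spread, drawn independently between arrays, of which 200 were changed, 50 per fold. Of these it recovered 64% at a fold of 1.5, 84% at 2, 96% at 4 and 100% at 8, with 12 false calls among all features. The changed features were not drawn from the dimmest ones. With 200 true changes the adjusted threshold is also easier to pass than where few features change. These rates therefore need not hold for the real arrays, and they do not show how many real 2-fold changes were missed.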

Results

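Transcript levels were compared between 3 control cultures of the yeast Yarrowia lipolytica, strain Y4184Ura+, and 3 cultures of Y4184 lacking SNF1. In budding yeast SNF1 encodes the catalytic subunit of the AMP-activated protein kinase complex, which is needed for the expression of many glucose-repressed genes. The comparison asks which transcripts differ in level when this kinase is absent during growth on glucose. Each array gave 375596 gene spots and 13711 random spots. The median gene spot read between 4356 and 5084 on the 6 arrays, 25.9 to 31.2 times the median random spot. At most 68 gene spots per array were saturated. Between 6618 and 6635 of the 6708 features were above background per array, and 6614 were above background on all 6 arrays.

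YALI00S00002794 had a log2 signal of 12.98 ± 0.14 (SD, n = 3) in the control and of 6.92 ± 0.05 (SD, n = 3) in the snf1 deletion, where it was not above background on any array. On the background-corrected scale it was at least 55.9-fold lower in the deletion cultures. The measured log2 difference was -6.07 ± 0.09 (SE) on that scale, with an adjusted p of 2.85e-06 in limma, and -5.30 without background correction; with the deletion arrays at background, neither is an exact size. It was the only feature above background on all 3 controls and on no deletion array, and 0 features showed the opposite pattern. All 14 of its probes, at positions 371 to 1674 of the target sequence, were above background on each control array, at scanner signals of 2973 to 24547. On the deletion arrays the same probes read 147 to 286, and 1, 2 and 2 of the 14 exceeded the 95th percentile of the random spots on replicates 1, 2 and 3. When each of the 93899 probes was tested on its own in limma, 14 fell with an adjusted p under the threshold and all 14 belonged to YALI00S00002794. The files do not say which gene this feature represents. The feature that represents SNF1 could therefore not be looked up, and the labels were not checked by the deleted gene's name.

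**Figure D1:**
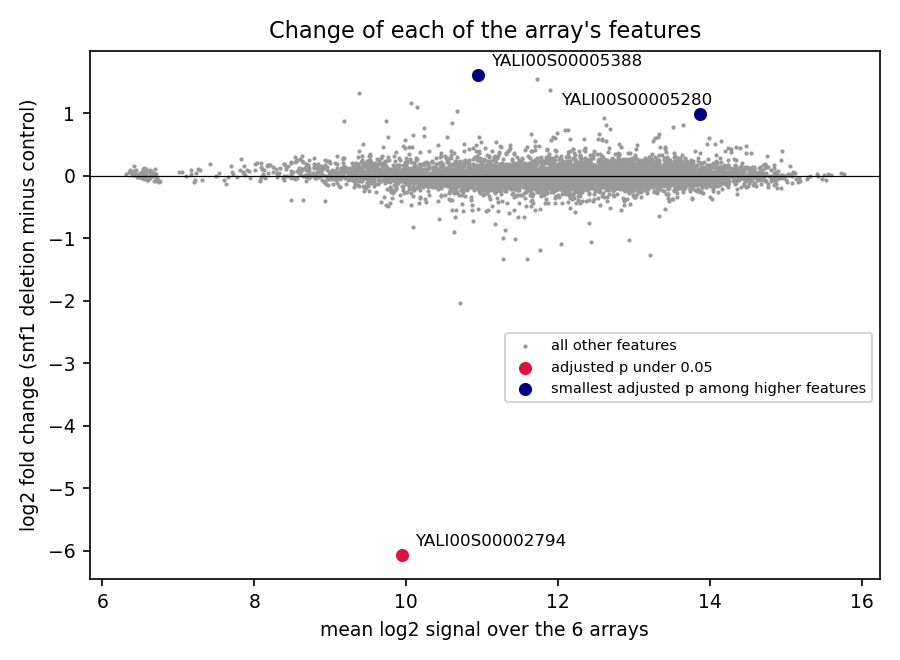
Log2 fold change (snf1 deletion minus control) against mean log2 signal over the 6 arrays, 1 point per feature (n = 3 arrays per group). YALI00S00002794 lies at -6.07, far below the other features, and the features marked in blue, at 1.61 and 0.99, have the smallest adjusted p among those higher in the deletion (0.069).

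**Figure D2:**
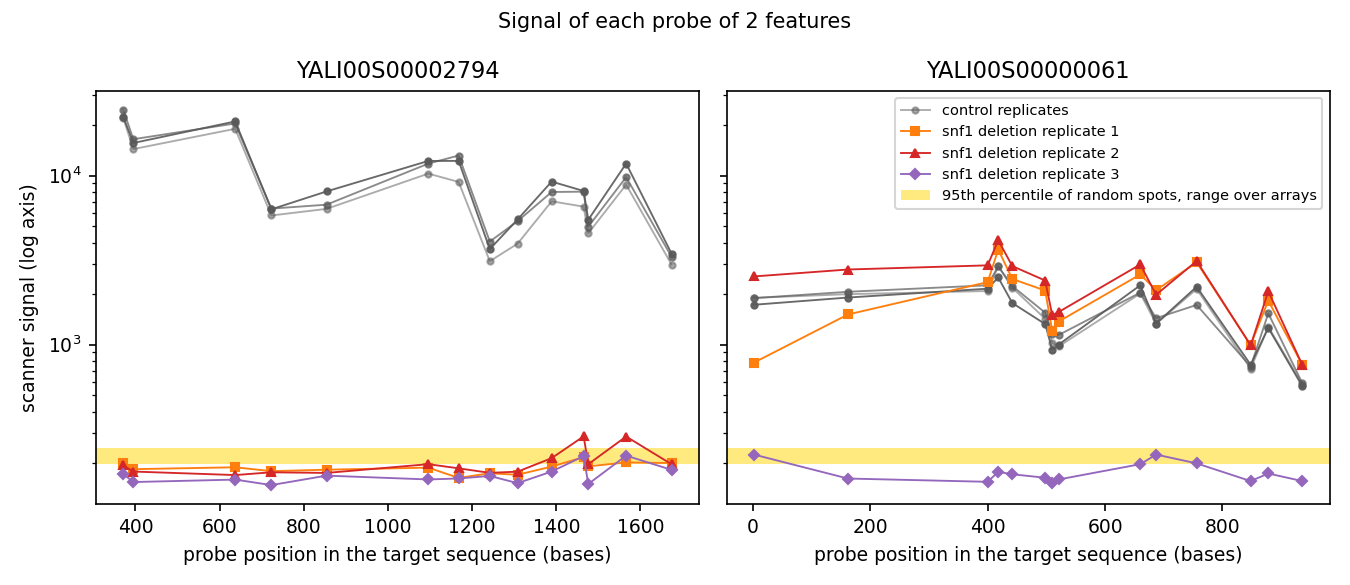
Scanner signal (log axis) of the 14 probes of YALI00S00002794 and of YALI00S00000061 against probe position in bases, 1 line per array; the band spans the 95th percentiles of the random spots of the 6 arrays. The first feature is at background on all 3 deletion arrays and the second, chosen after its values were seen, on replicate 3 of the deletion alone.

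No other feature passed the threshold. In limma 0 features rose and 1 fell, YALI00S00002794, which was also the only feature that passed the adjusted threshold with a change of at least 2-fold. At an unadjusted p under 0.05 there were 290 features, 198 higher and 92 lower, where 335 would be expected of 6708 if none differed. In the authors' deposited table, tested the same way, 0 rose and 1 fell, and 305 features had an unadjusted p under 0.05. The share of features at an unadjusted p under 0.05, 4.32% with all arrays, depended on single arrays. It was 1.70% without control replicate 2, 7.93% without control replicate 3 and 16.7% without replicate 1 of the deletion. Of the 6614 features above background on all 6 arrays, 6268 (94.8%) had, in limma, a 95% interval of the log2 fold change that lay entirely between -1 and 1. These intervals are not adjusted for the number of features and refer to the measured signal, in which changes of dim features are compressed. The median absolute log2 fold change was 0.08 and the median SE was 0.10. The arrays of the groups did not overlap for 755 features (11.3%), against 10% expected by chance for 3 against 3. The order of image analysis followed the groups, so an effect of that order and the deletion cannot be told apart.

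The features with the smallest adjusted p among those higher in the deletion were YALI00S00005388 and YALI00S00005280, named after their values were seen. YALI00S00005388 had a log2 signal of 10.15 ± 0.18 (SD, n = 3) in the control and of 11.76 ± 0.21 (SD, n = 3) in the deletion, a log2 difference of 1.61 ± 0.14 (SE). YALI00S00005280, one of the brighter features, had a log2 signal of 13.38 ± 0.14 (SD, n = 3) and of 14.37 ± 0.06 (SD, n = 3), a difference of 0.99 ± 0.09 (SE). Every deletion array was above every control array for both, yet both missed the threshold, with an adjusted p of 0.069 in limma. In the probe-by-probe test 4 of the 93899 probes rose, and all 4 were among the 14 probes of YALI00S00005388. The probes of a feature read the same RNA samples, so this is no separate support for it. In total 7 features were estimated at least 2-fold higher, and the groups did not overlap for any of these 7. Among the 7 were YALI00S00005399 and YALI00S00005401, for which replicate 1 of the deletion was the highest array. It read 11.73 against 10.25 and 10.09 on replicates 2 and 3 for the former, and 11.21 against 10.35 and 10.39 for the latter. Besides YALI00S00002794, 10 features were estimated at least 2-fold lower, but the groups overlapped for 7 of these 10. Control replicate 3 was the lowest control for 8 of the 10, and for 6 it lay more than 1 log2 unit below the mean of the other controls.

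The snf1 deletion cultures did not form a tight group. Replicates 2 and 3 correlated at 0.991 across features, whereas replicate 1 correlated with them at 0.953 and 0.962. With the controls replicate 1 correlated at 0.964 to 0.981, the highest with control replicate 3. The controls correlated with one another at 0.985 to 0.989. On replicate 1 of the deletion, 205 features were at least 2-fold lower than the median of the other 5 arrays and 22 were at least 2-fold higher. Of these 205, 178 (86.8%) were dimmer than the median feature. On the other arrays at most 20 were lower and at most 21 higher by as much. YALI00S00002794 was at background on replicate 1 as on the other deletion arrays.

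Without replicate 1 of the deletion, 2 features rose and 7 fell in limma, and 1 of these 9 was shared with the comparison of all arrays. The 2 that rose were YALI00S00005388, with a log2 difference of 1.49 ± 0.11 (SE) and an adjusted p of 0.012, and YALI00S00005280, with 0.97 ± 0.10 (SE) and an adjusted p of 0.044. Besides YALI00S00002794, 6 features fell, by 0.80 to 1.20 on the log2 scale. Over all 17 alternatives run, the adjusted p in limma ranged from 0.012 to 0.99 for YALI00S00005388 and from 0.019 to 0.99 for YALI00S00005280. Both values of 0.99 came from the replicate block. Under the other settings the highest adjusted p in limma was 0.38 for YALI00S00005388 and 0.62 for YALI00S00005280. For YALI00S00005490 the range was 0.0083 to 0.999985 in limma. YALI00S00005490, chosen after its values were seen, had the smallest adjusted p in limma (0.0083) of the 6 lower features. It had log2 signals of 10.83, 10.79 and 10.72 on the controls and of 9.62 and 9.56 on replicates 2 and 3 of the deletion, but of 11.06 on replicate 1. The same held for all 6: replicate 1 lay above every control array, by 0.09 to 0.51 over the control mean. These 6 passed only with replicate 1 left out, so a differing value on it is in part built into their choice. With all arrays YALI00S00005490 differed by -0.70 ± 0.40 (SE, adjusted p = 0.90 in limma).

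**Figure D3:**
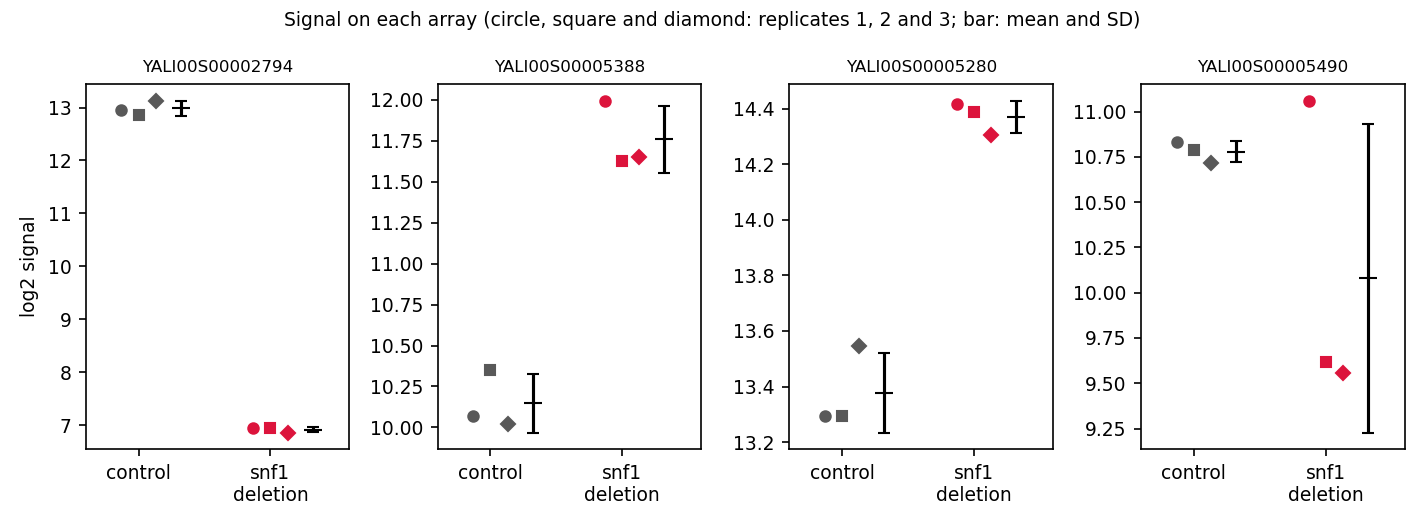
Log2 signal of 4 features on each array (circle, square and diamond for replicates 1, 2 and 3), with the mean and SD of each group (n = 3) beside the points; each panel has its own vertical scale and the axes do not start at 0. YALI00S00005388 and YALI00S00005280 are higher on all deletion arrays, and YALI00S00005490 is lower on replicates 2 and 3 of the deletion only.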

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

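The array weights were chosen after the data were seen; all other alternatives were planned. YALI00S00002794 stayed lower and past the threshold under all 17 alternatives run, with an adjusted p from 3.19e-07 to 0.00386 in limma. Its measured log2 differences ran from -8.23 (the deposited table) to -5.30 (no background correction); it was not above background on the deletion arrays, so these sizes depend on the floor of each setting and are not exact. The count of features higher was 0, and became 1 with the mean of probes and 1 with every spot in the median polish, 2 with an intensity trend and robust estimation, and 4 with array weights, which gave replicate 1 of the deletion a weight of 0.23. The count at least 2-fold higher was 1 under each of these 4 settings and 0 otherwise, except as follows. With each array left out in turn, the counts ranged from 0 to 2 features higher and from 1 to 7 lower, and from 0 to 1 and from 1 to 3 for changes of at least 2-fold. All of the larger values came from leaving out replicate 1 of the deletion, which also took the features with an unadjusted p under 0.05 from 290 to 1117; the cause was not tested. YALI00S00005388 kept its direction under all 17 alternatives (1.48 to 1.86) and passed the threshold under 5 of them, YALI00S00005280 kept its direction (0.95 to 1.07) and passed under 3, and YALI00S00005490 kept its direction (-1.19 to -0.44) and passed under 1. With the replicate block, 0 features rose, 1 fell and 185 had an unadjusted p under 0.05. Deviations of same-numbered arrays from their group means correlated at -0.31, -0.02 and -0.35, so the numbers were not taken to pair the samples, and 0 of the 6 arrays correlated best with the array of its own number. Tests of the gene lists, with camera or fry, could not be run under any setting because no feature has a gene name here. A dim feature has little room to fall: 71 features were above background on no array.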

Other observations

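The tests of neighbouring spots were planned before their results were seen; all other tests in this part were chosen after the result was seen. The tests of brightness and of transcript ends for replicate 1 replaced earlier forms: removal of a trend with the brightness of probes left an SD of 0.456 and with that of features 0.433, from 0.439 before, which moved too little to decide, and the first test of probe position could not have changed the SD. Correlations between odd and even probes and along the running numbers were also tested as explanations at first and are given as values only. A group of 5 features with consecutive running numbers, 5398 to 5402, was higher on replicate 1 of the deletion than the control mean, by 1.70 to 2.71 on the log2 scale. On replicates 2 and 3 the same features differed from the control mean by -0.50 to 0.91, and the highest SD of the controls was 0.21. Of the 5, 3 were above every control on all 3 deletion arrays. None of the 5 passed the threshold between the groups (adjusted p of 0.69 to 0.93 in limma). Along the running numbers, log2 fold changes of successive features correlated at 0.15 over 6707 features, YALI00S00002794 left out (permutation p = 0.0001, the smallest that 10000 shuffled orders can give; the highest shuffled value was 0.05). The difference between replicate 1 and the mean of replicates 2 and 3, within the deletion group, correlated as much (0.16), as did the mean log2 signal (0.17), so the correlation is not particular to the comparison of the groups. These correlations are across features, which are not independent replicates.

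Of the 71 features above background on no array, 35 were among the last 42 running numbers, a window chosen after the values were seen, and 36 among the other 6666. The remaining 7 of those 42 were above background on all 6 arrays. The files do not say what the last features represent.

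YALI00S00000061, chosen after its values were seen, was at background on replicate 3 of the deletion alone. Its log2 signal was 10.50 ± 0.04 (SD, n = 3) in the control, 11.15 and 11.04 on replicates 1 and 2 of the deletion, and 6.85 on replicate 3, at least 12.2-fold below the mean of the other 5 arrays on the background-corrected scale. All 14 of its probes were above background on each of those 5 arrays and 3 of 14 were on replicate 3, where they read 152 to 223. No other feature with signals of this size was lost on a single array: the 12 features below background only on replicate 1 of the deletion had signals of at most 513 elsewhere, and the 1 below background only on control replicate 1 of at most 276. Because its 56 spots lie across the whole array, a local defect of the array surface would have to reach many places, and the 1285 neighbouring spots of other features changed by a median of 0.0280 on the log2 scale, which argues against it. A loss or change of this locus in that culture, or a silent gene there, may each give this picture, and neither was tested since no DNA measurement was used here.

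The same test for YALI00S00002794 gave a median log2 change of -0.00474 over 1306 neighbouring spots, while the least changed of its own 56 spots fell by 4.53, which argues against a local defect of the array surface. Its loss of signal over 14 probes on 3 of 3 deletion arrays is what a deleted gene would give, and it may be the SNF1 feature, but the files offer no name with which to test this. The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05: the real split gave 1 feature past the threshold, and 1 of at least 2-fold, and the highest other split gave 0 of either kind. By unadjusted p under 0.05 the real split gave 290 features and the other 9 splits gave 23 to 1092 (median 243), 4 of them more than the real split and 5 fewer. The highest, picked out after all were seen, set control replicate 1 with replicates 2 and 3 of the deletion against the rest, and a count several times the real one points to a structure of the samples.

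Replicate 1 of the deletion stood apart from replicates 2 and 3: over features the SD of its deviation from their mean was 0.44, against at most 0.22 for a control array set against the other controls. Chosen without this array, 1 feature was above background on all 3 controls and on neither replicate 2 nor 3, YALI00S00002794, and its median signal on replicate 1 was 187, below the 215 of the random spots' 95th percentile, which argues against a control culture under a mutant label. Loss of signal of dim probes may account for a part of the deviation. Before normalization the 5th percentile of the gene spots read 347 on this array and 555 to 666 on the others. The brightness values that follow were taken after quantile normalization, which gives all arrays the same spot distribution. The SD of the deviation was 2.42 times as large over the dimmer features as over the brighter ones (controls at most 1.34 times), a ratio without direction. Of the 205 features 2-fold lower on this array, 178 were dimmer than the median feature. Over the 3354 brighter features the SD was still 0.236 (controls at most 0.183), which argues against such a loss as the whole cause. Here and in the test of ends below, 1 array was set against 3 controls, too few to show how far single cultures stray. Within features the deviation changed by -0.149 per log2 unit of probe brightness (-0.0255 to 0.0447 on the controls). The brighter probes of a feature were thus the lower ones on this scale. Since the offset and the residual background compress the falls of dim probes, this sign does not decide on a loss of their signal. RNA of other integrity was tested only as a change confined to 1 end of the probed stretch. In that form it is argued against as the whole cause, since the SD over the less affected 7 probes was 0.44 (controls at most 0.22). A loss of integrity that changes all probes of a transcript would go unseen in this test and stays open. A part played by an end effect also stays open. The SD over the first 7 probes was 0.48 and the deviation changed by 0.00468 per probe rank (-0.00128 to 0.000989 on the controls). The deviations of odd-numbered and even-numbered probes correlated at 0.97 across features, which are not independent replicates. A difference in growth state, in the strain behind the title number 43, or in hybridization by base composition stays open and untested.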
